A study of Homo sapiens with 6 samples.

How the data were processed

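Total RNA of CAL-27 cells was extracted with Trizol and sequenced as single-end 50-base reads on a BGISEQ-500, per the labels' protocols, in 3 parental and 3 sphere libraries. The authors deposited 1 table of TPM (transcript abundance scaled to a fixed total per library) for 17110 genes, per the file headers, with values to 2 decimals with the same sum in each library. The submitters' processing notes name HISAT and Bowtie2 without versions, and the genome build GRCm38.p6, which is a mouse build. The gene IDs are nevertheless human: 17052 of the 17110 Entrez Gene IDs matched the human RefSeq table of GRCh38.p14, 16805 of them with the same symbol. The build behind the values is therefore unclear, and no coordinates are given. The counting tool, the annotation, the RNA selection and the use of strand are not given in the sources used here, so genes that overlap or have near-identical copies are uncertain.

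The table names its columns Control and Sphere with a replicate number. The series has 2 groups, and Control was taken as parental. TPM keeps no depth, so the depth of each library is unknown and the precision rests on the spread between the 3 libraries of a group.

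Genes with a mean TPM of at least 1 over the 6 libraries (12261) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), sphere minus parental, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A difference on this scale understates the change of genes with low TPM. The test rested on 4 residual degrees of freedom and a median of 5.26 prior degrees of freedom. Of 30 gene lists, the 28 with at least 3 tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list's own genes move one way. A call lost with an estimated correlation need not reflect correlated genes. For the immediate early list the estimate was -0.0015, below the preset 0.01, yet the camera adjusted p went from 5.0e-05 to 0.0658. Members' calls were also adjusted over the list alone. Of the 618 list entries, 10 genes are in more than 1 list.

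The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap, with a mean of at least 5 TPM in the higher group. It also takes every tested stem cell marker, the member with the largest rise and fall of each other list among those past the threshold, and the most abundant fibroblast, leukocyte and endothelial marker. A few genes that the rule takes are not reported here. Genes named outside the rule are the stem cell markers below the filter, COL1A2, COL3A1 and PTPRC, and in the closing observations LUM, PDGFRA, HLA-DRA, CD74, HLA-DQB1 and the genes at the ends of chromosome blocks.

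For the chromosome blocks, 12239 tested genes were ordered along the chromosomes of the RefSeq table and divided into 307 blocks of about 40 neighbours. Each block's median change was compared with 1000 permutations of the gene order, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. GC content and transcript length came from GENCODE 29. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 TPM, median-of-ratios scaling, a robust variance prior, array weights, no trend, a replicate block and leaving out each library. Tested on simulated data for this comparison, with 50 of the 12261 genes changed at each size, limma recovered 46%, 80%, 100% and 96% of changes of 0.25, 0.5, 1 and 2 on the log2 scale, and called 5 of 12061 unchanged genes. In the real data 10221 genes passed, far more than were changed in the simulation. The adjustment is then less strict, so the simulated shares of recovered and of wrongly called genes do not carry over.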

Results

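The transcriptomes of CAL-27 cells grown in adhesion (parental) and of sphere cells, labelled as the same line and obtained by suspension culture, were compared. Whether both groups came from the same stock of cells was not tested, so differences between them need not come from the culture form. CAL-27 is an established human cell line from a squamous cell carcinoma of the tongue, and per the series' design text the suspension culture served to isolate cancer stem cells. In all, 6 RNA-seq libraries of total RNA were available, 3 parental and 3 sphere. Values were TPM, which keep no sequencing depth, so the depth behind each value is unknown and no counting interval is given. Each library listed between 15045 and 15448 genes above 0. Across genes, log2(TPM + 1) correlated at r = 0.995 to 0.997 within groups and at r = 0.840 to 0.842 between groups (genes are not independent replicates). The labels do not state whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

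Sphere libraries held far more transcript of KRT14 and of SPRR genes than parental libraries and far less of VIM and CCL2. KRT14 (Entrez Gene 3861), a keratin of basal squamous epithelium, was at 4.69 ± 0.21 TPM in parental and 7705 ± 79.5 TPM in sphere libraries (SD, n = 3 each). VIM (Entrez Gene 7431), the intermediate filament of mesenchymal cells, was at 625 ± 4.4 TPM in parental and 2.11 ± 0.34 TPM in sphere libraries. CCL2 (Entrez Gene 6347), a monocyte-attracting chemokine, was at 2091 ± 76.4 TPM in parental libraries and at 0.24 TPM in each sphere library. Of 30 mitosis genes all 30 fell and of 30 replication genes 29 fell. In a histone list fixed with RNA selection in view, 12 of 13 tested genes rose. The camera calls of these 3 lists were lost with an estimated correlation, at adjusted p = 0.0758, 0.0623 and 0.134. The stem cell markers moved in both directions.

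Of 12261 genes tested with limma, 10221 (83.4%) passed an adjusted p of 0.05, with 4309 higher and 5912 lower in sphere libraries. The 2 groups did not overlap in 84.6% of tested genes, where chance gives 10%. At least 2-fold differences on the log2(TPM + 1) scale were found for 3336 genes, 1534 higher and 1802 lower, so that 46.0% of them were higher. With median-of-ratios scaling in place of TPM alone, 1833 were higher and 1427 lower (56.2% higher). That scaling shifted the median log2 change of all tested genes by 0.14, from -0.13 to 0.01, and medians of gene lists are therefore given relative to all tested genes. Neighbouring genes in 10 chromosome blocks shifted together (values under the closing observations), and without the 406 genes of these blocks, an alternative chosen after seeing the data, 9848 genes passed.

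**Figure D1:**
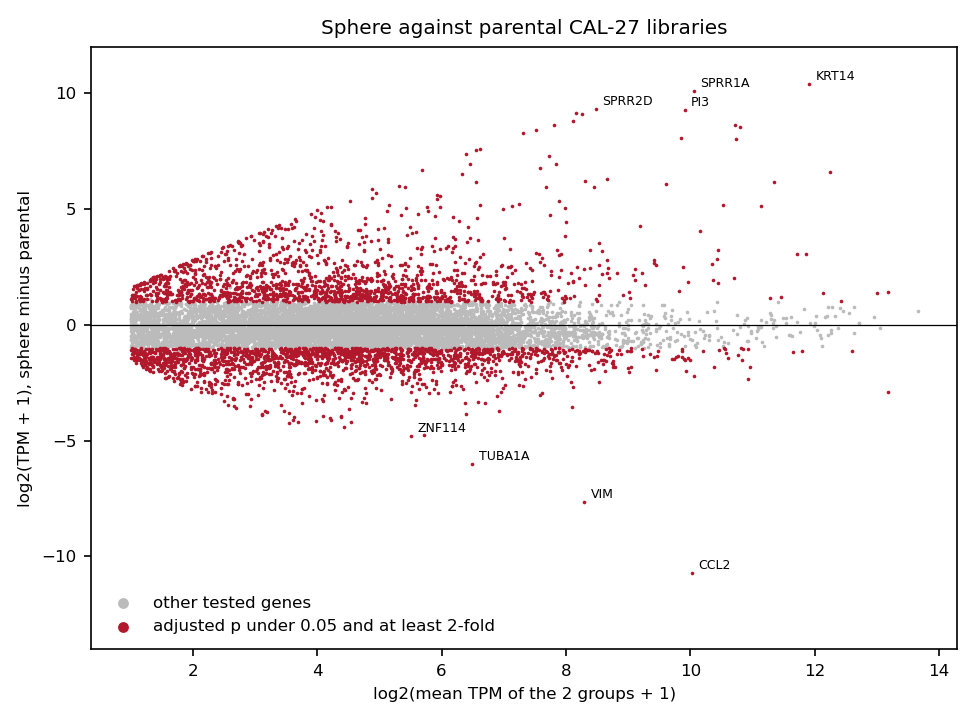
Difference in log2(TPM + 1) between sphere and parental libraries (3 each) against the log2 mean TPM of the 2 groups, 1 point per tested gene. Red points are the 3336 genes past an adjusted p of 0.05 in limma with at least a 2-fold difference, and the 4 genes with the largest rise and fall among the named genes are labelled, KRT14 at the top and CCL2 at the bottom.

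The 8 largest rises were, besides KRT14, in genes of the cornified envelope and of epithelial defence. SPRR1A, a cornified envelope precursor, was at 0.98 ± 0.49 TPM in parental and 2127 ± 94.0 TPM in sphere libraries. PI3, an elastase inhibitor of stratified epithelium, was at 2.10 ± 0.38 and 1918 ± 34.8 TPM, and S100A8, a calcium-binding protein of calprotectin, at 7.60 ± 1.80 and 3372 ± 19.3 TPM. The other 4 were SPRR2D, SPRR2E, SPRR2A and SPRR2G, at 716, 613, 552 and 573 TPM in sphere libraries. SPRR2G was listed at 0 in each parental library, and the others at no more than 0.41 TPM. The SPRR2 genes are near-identical copies, and how reads were divided between them is uncertain. After CCL2 and VIM, the largest falls were in TUBA1A, an alpha-tubulin (177 ± 16.9 to 1.74 ± 0.30 TPM), ZNF114 (86.7 ± 4.2 to 2.15 ± 0.30 TPM), PLAT, tissue plasminogen activator (99.96 ± 3.13 to 2.75 ± 0.43 TPM), CD70, a ligand of the tumour necrosis factor family (40.3 ± 4.4 to 0.96 ± 0.50 TPM), TNFRSF9 (21.2 ± 1.1 to 0.18 ± 0.02 TPM) and HSPB8, a small heat shock protein (43.1 ± 0.3 to 1.41 ± 0.43 TPM). The adjusted p in limma was at most 6.8e-09 for each of these 16 genes.

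Of 14 stem cell markers tested, 7 rose, 6 fell and SOX2 did not pass, and the counts adjusted over the list alone were the same. As a list they did not stand apart from other genes (camera adjusted p = 0.342, median 0.22 relative to all genes). With only genes of at least 5 TPM on average tested, the list passed (camera adjusted p = 0.0158, median 1.37). That filter removed ALDH1A1, POU5F1, NES and ABCG2, which fell, and SOX2, and kept every marker that rose. The pass therefore does not show that the markers rose as a group. With an estimated correlation and the usual filter its adjusted p was 0.587. CD24 rose from 6.73 ± 0.62 to 272 ± 15.1 TPM, CD44, the hyaluronan receptor used to sort stem-like cells of head and neck carcinoma, from 537 ± 13.7 to 2086 ± 32.6 TPM, and ITGA6 from 172 ± 5.0 to 567 ± 25.1 TPM. SOX9 rose from 10.8 ± 1.3 to 51.2 ± 3.6 TPM and TP63 from 65.5 ± 1.2 to 156 ± 10.2 TPM. CD24 and the ribosomal protein and histone genes named further on have pseudogenes or close copies, so their share of reads is uncertain. The rises of KLF4 (17 ± 0.2 to 21 ± 1.1 TPM) and MYC (77.7 ± 3.2 to 86.9 ± 3.2 TPM) were small. ALDH1A3 fell from 48.9 ± 2.9 to 25.3 ± 1.0 TPM, ALDH1A1 from 2.36 ± 0.60 to 0.37 ± 0.13 TPM, POU5F1 from 5.73 ± 0.62 to 2.01 ± 0.21 TPM, NES from 5.26 ± 0.43 to 1.16 ± 0.12 TPM, ABCG2 from 1.77 ± 0.31 to 0.78 ± 0.12 TPM and BMI1 from 17.3 ± 0.6 to 13.2 ± 1.0 TPM. SOX2 was at 1.70 ± 0.44 and 1.73 ± 0.44 TPM (limma adjusted p = 0.937). PROM1, LGR5, NANOG, LIN28B and THY1 were below the expression filter.

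**Figure D2:**
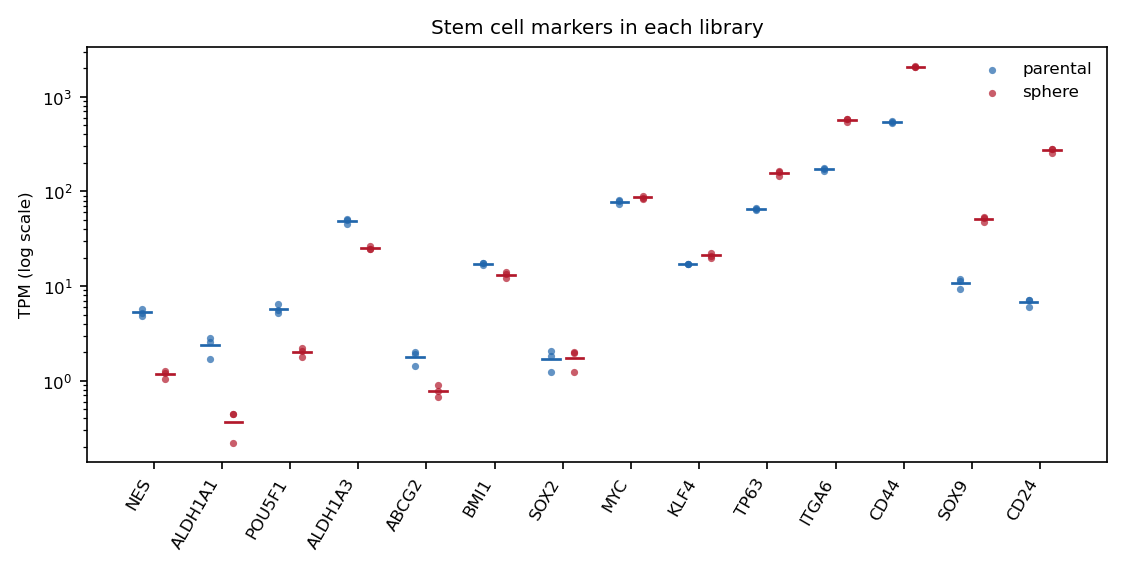
TPM (log axis) of the 14 tested stem cell markers in each of the 3 parental (blue) and 3 sphere (red) libraries, with a line at each group's mean. CD24, CD44, ITGA6, SOX9 and TP63 lie higher in all 3 sphere libraries, and NES, ALDH1A1, POU5F1 and ALDH1A3 lower.

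Genes of squamous differentiation and of the basal keratinocyte layer rose together. In the squamous differentiation list 25 of 26 tested genes rose and KLK6, a kallikrein protease, fell from 5.50 ± 0.38 to 2.50 ± 0.52 TPM. The list median was 4.49 above all genes on the log2 scale (camera adjusted p = 1.5e-10, and adjusted p = 0.0424 with an estimated correlation). Of 14 basal keratinocyte genes 13 rose and CAV1, the main protein of caveolae, fell from 555 ± 8.2 to 348 ± 6.9 TPM (median 2.30, camera adjusted p = 8.9e-08, adjusted p = 0.0658 with an estimated correlation). Of 20 epithelial adhesion genes 18 rose, led by the desmosomal PKP1 (5.47 ± 0.36 to 403 ± 9.0 TPM). The other 2 fell, among them EPCAM (311 ± 9.0 to 160 ± 12.8 TPM). The list median was 1.26 (camera adjusted p = 2.3e-06, adjusted p = 0.0758 with an estimated correlation). These counts were the same when adjusted over the list alone and with median-of-ratios scaling.

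The mesenchymal list leaned lower in sphere libraries but did not pass in camera. Of 13 tested regulators and markers of the epithelial to mesenchymal transition 4 rose and 8 fell (camera adjusted p = 0.437). At least 2-fold, 2 rose and 5 fell, and the list median was -0.33 relative to all genes. VIM had the largest fall, while SNAI2, a transcription factor of the SNAIL family, rose from 13.6 ± 1.1 to 83.2 ± 2.1 TPM. In the partial transition list, fixed from secreted and matrix genes, 11 of 16 rose and 3 fell (median 2.20, camera adjusted p = 4.5e-04, adjusted p = 0.145 with an estimated correlation). The collagenase MMP1 rose from 5.88 ± 0.66 to 1841 ± 40.2 TPM and the matrix protein TNC fell from 289 ± 6.1 to 76.3 ± 1.3 TPM. Of 22 matrix and integrin genes 13 rose, such as the collagen receptor subunit ITGA2 (21.7 ± 2.2 to 172 ± 5.5 TPM), and 6 fell, such as COL4A1 of the basement membrane (29.3 ± 1.4 to 5.77 ± 0.85 TPM), with a median of 0.78 (camera adjusted p = 0.0294, adjusted p = 0.618 with an estimated correlation). Markers of other cell types were mostly under the filter. Of the fibroblast markers 3 were tested, where COL1A1 rose (8.15 ± 0.06 to 16.1 ± 0.9 TPM), PDGFRB fell (2.63 ± 0.17 to 0.087 ± 0.045 TPM), and the median was above 0 and the mean below. COL1A1, COL1A2 and COL3A1 together came to 1.41 to 1.45% of the VIM TPM in parental libraries. The leukocyte marker PTPRC was listed at 0 in each parental library, and CD68, a lysosomal protein abundant in macrophages, rose from 48.1 ± 2.6 to 176 ± 3.1 TPM while the other 2 tested leukocyte markers did not pass. Of 2 endothelial markers tested, CDH5 fell from 11 ± 0.3 to 0.01 ± 0.017 TPM, and EGFL7, which lies in one of the shifted blocks, was at 9.70 ± 0.66 and 11.5 ± 1.0 TPM (limma adjusted p = 0.0279, lost when parental replicate 1, sphere replicate 1 or sphere replicate 3 was left out, where it was at most 0.0969, and with no filter, where it was 0.0505).

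In the 2 cell cycle lists, all 30 mitosis genes fell, with the transcription factor FOXM1 going from 108 ± 4.6 to 13 ± 0.5 TPM (median -1.85, camera adjusted p = 3.4e-10, adjusted p = 0.0758 with an estimated correlation). Of 30 replication genes 29 fell (median -1.58, camera adjusted p = 5.7e-09, adjusted p = 0.0623 with an estimated correlation). No member of either list rose, and both counts held with median-of-ratios scaling. In the same libraries 12 of 13 tested replication histone genes rose, such as H2BC21 (2.50 ± 0.38 to 63.1 ± 0.7 TPM; median 2.63, camera adjusted p = 7.3e-05, adjusted p = 0.134 with an estimated correlation). The remaining one, H4C3, was at 3.72 ± 1.13 and 1.20 ± 2.07 TPM, and its call (limma adjusted p = 0.022) was lost when parental replicate 1 or 3 or sphere replicate 1 or 3 was left out, where it was at most 0.0942, with no filter (0.0631) and with a robust variance prior (0.104). Its log2 difference of -1.47 ranged from -2.21 to -1.11 with 1 library left out. Histone transcripts largely lack a poly(A) tail, and how the RNA was selected is not given in the sources used here. The histone list was fixed with RNA selection in view, and its rise does not tell whether replication changed.

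Energy metabolism genes were mostly lower in sphere libraries. Of 18 glycolysis genes 16 fell, for instance the enolase ENO2 (78.1 ± 1.6 to 11.9 ± 0.9 TPM), and 2 rose, among them PFKL (53.1 ± 1.2 to 98.0 ± 4.7 TPM). The list median was -0.99 (camera adjusted p = 5.2e-04, adjusted p = 0.146 with an estimated correlation). Of 30 oxidative phosphorylation genes 27 fell and 1 rose, or 2 rose adjusted over the list alone, and with median-of-ratios scaling 24 fell and 3 rose (median -0.56, camera adjusted p = 5.0e-05, adjusted p = 0.0758 with an estimated correlation). SDHA fell from 389 ± 3.9 to 119 ± 2.6 TPM and CYC1 rose from 186 ± 11.7 to 235 ± 3.9 TPM, and both lie in shifted chromosome blocks. Cholesterol synthesis genes went the other way, with 17 of 24 rising and 6 falling (median 1.02, camera adjusted p = 5.1e-04, adjusted p = 0.226 with an estimated correlation).

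Among the signalling and stress lists, 14 of 16 immediate early genes rose, led by ZFP36 (11.4 ± 0.9 to 121 ± 6.3 TPM), and 2 fell, among them JUN (55.6 ± 0.8 to 45.1 ± 2.4 TPM). The list median was 1.45 (camera adjusted p = 5.0e-05, adjusted p = 0.0658 with an estimated correlation). Of 17 NOTCH pathway genes 12 rose, such as HES2 (1.59 ± 0.11 to 51.3 ± 0.4 TPM), and 4 fell, such as the DNA-binding partner RBPJ (44.7 ± 1.5 to 18.0 ± 0.6 TPM). The list median was 1.19 (camera adjusted p = 0.0029, adjusted p = 0.232 with an estimated correlation). Of 19 unfolded protein response genes 16 fell, including the chaperone CALR (1761 ± 58.9 to 381 ± 14.6 TPM), and 3 rose, including DNAJB9 (9.88 ± 0.79 to 28.5 ± 1.5 TPM). Their median was -1.01 (camera adjusted p = 0.0022, adjusted p = 0.105 with an estimated correlation). Of 21 NRF2 and aldo-keto reductase genes 16 fell, including PIR (50.3 ± 2.5 to 9.09 ± 0.76 TPM), and 4 rose, including AKR1C1 (1.64 ± 0.13 to 12.7 ± 0.7 TPM). Their median was -0.64 (camera adjusted p = 0.0294, adjusted p = 0.266 with an estimated correlation). AKR1C1 has near-identical family members and its share of reads is uncertain. Apart from oxidative phosphorylation, the counts of every called list were the same adjusted over the list alone. Some changed with median-of-ratios scaling. The genes that fell then numbered 14 in the glycolysis list, 14 in the unfolded protein response, 15 in the NRF2 list and 1 among immediate early genes. Cholesterol synthesis then had 18 rising and 4 falling, the partial transition list 12 and 2, and the matrix and integrin list 14 and 5.

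**Figure D3:**
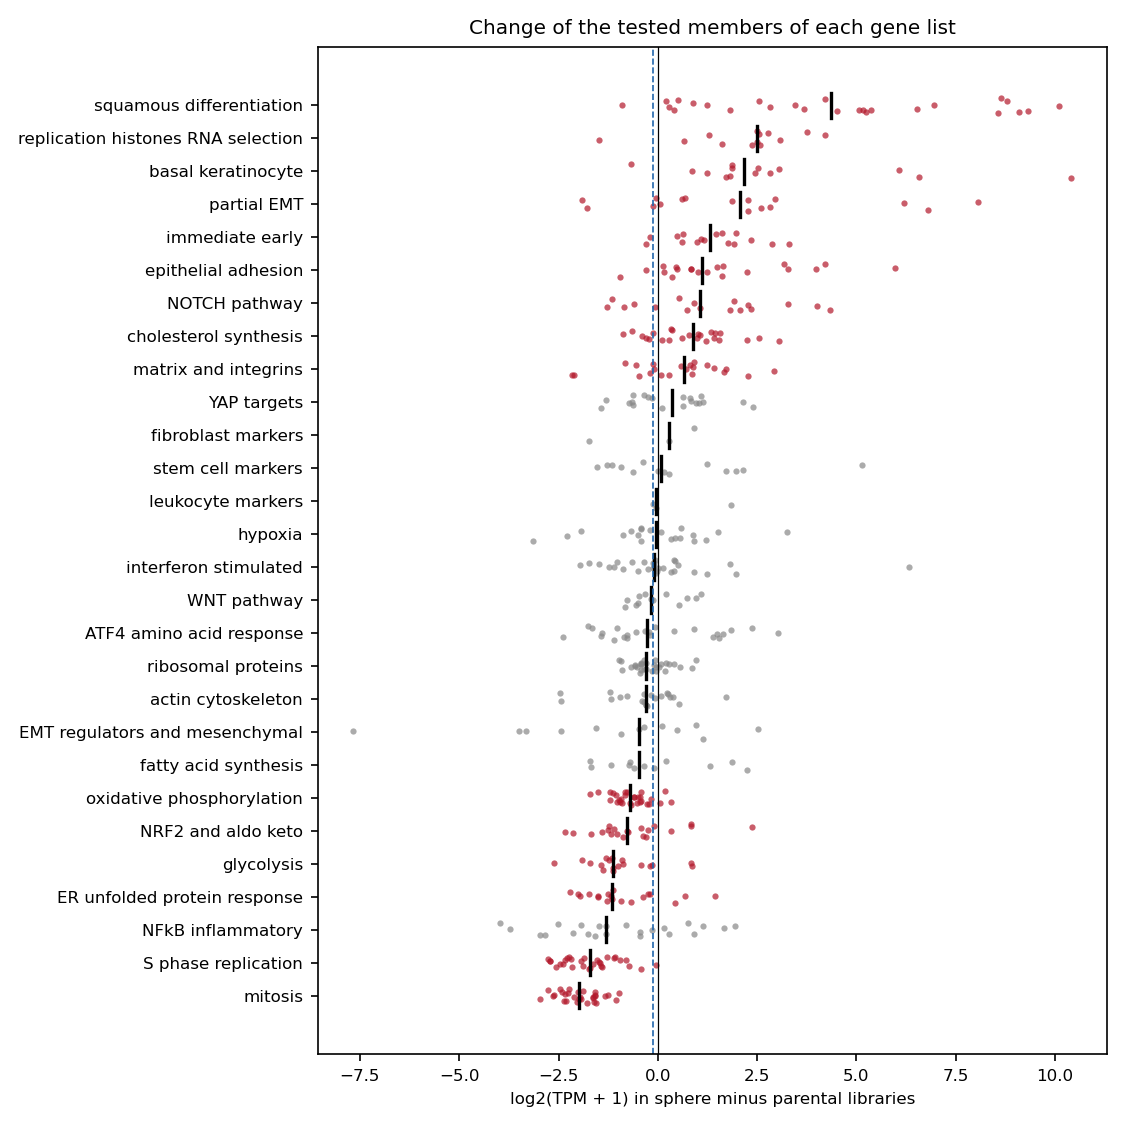
Difference in log2(TPM + 1) between sphere and parental libraries (3 each) for each tested gene (1 point) of the 28 gene lists tested, with a black bar at the list median and a dashed line at the median of all tested genes (-0.13). Lists in red are the 15 past an adjusted p of 0.05 in camera, from squamous differentiation at the top to mitosis at the bottom.

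The other 13 lists tested did not pass in camera. Besides the stem cell, mesenchymal, fibroblast and leukocyte lists described above (camera adjusted p = 0.729 and 0.437 for the last 2), the NF-kB inflammatory list came closest, with 16 of 23 genes lower and 7 higher (adjusted p = 0.0552). This call depended on the setting: the list passed with no filter, with a mean of at least 5 TPM, with median-of-ratios scaling and without sphere replicate 1 or sphere replicate 3 (adjusted p of 0.037, 0.0318, 0.0287, 0.0434 and 0.0406). With an estimated correlation it did not pass (adjusted p = 0.473). IL6 fell from 38.4 ± 1.3 to 1.5 ± 0.15 TPM and CCL20 rose from 19.1 ± 3.5 to 75.3 ± 7.3 TPM. Of 20 hypoxia genes 9 rose, including NDRG1 (63.2 ± 4.2 to 606 ± 16.9 TPM, in a shifted block), and 10 fell, including the carbonic anhydrase CA9 (47.7 ± 2.9 to 4.53 ± 0.88 TPM; adjusted p = 0.729), or 10 and 9 with median-of-ratios scaling. Of 30 interferon-stimulated genes 11 rose, led by IFI27 (9.55 ± 4.12 to 796 ± 17.1 TPM, in a shifted block), 12 fell, including IFIT2 (23.7 ± 1.2 to 5.36 ± 0.44 TPM), and 7 did not pass (adjusted p = 0.926), while with median-of-ratios scaling 13 rose and 9 fell. YAP targets had 10 genes up, including NT5E (98.5 ± 3.2 to 523 ± 12.3 TPM), and 8 down, including ASAP1 (71.2 ± 0.6 to 25.8 ± 0.8 TPM; adjusted p = 0.269). Of 21 actin cytoskeleton genes 6 rose and 13 fell, including TPM1 (458 ± 24.6 to 82.3 ± 4.4 TPM; adjusted p = 0.384). Of 30 ribosomal protein genes 8 rose and 18 fell, or 10 and 15 with median-of-ratios scaling (adjusted p = 0.384), with RPL8, in a shifted block, going from 1849 ± 36.5 to 3618 ± 32.7 TPM and RPS14 from 961 ± 19.9 to 489 ± 9.2 TPM. The amino acid response had 9 of 24 genes up, including CHAC1 (1.16 ± 0.34 to 16.4 ± 1.6 TPM), and 13 down, including STC2 (46.6 ± 1.8 to 8.16 ± 0.31 TPM; adjusted p = 0.779). Fatty acid synthesis had 4 of 12 genes up, including SCD (140 ± 1.3 to 667 ± 14.1 TPM), and 7 down, including FADS1 (48.2 ± 2.6 to 13.9 ± 0.6 TPM; adjusted p = 0.729). The WNT pathway had 5 of 13 genes up, including WNT10A (5.26 ± 0.52 to 12.3 ± 1.0 TPM), and 7 down, including WNT4 (2.80 ± 0.31 to 1.17 ± 0.32 TPM; adjusted p = 0.926). With median-of-ratios scaling the genes up and down numbered 5 and 5 in the WNT list and 7 and 15 in the NF-kB list. They were 10 and 7 in the YAP list, 7 and 12 in the actin list and 10 and 12 in the amino acid response. The median, the mean or the direction of a set test differed in sign for the hypoxia, interferon, amino acid response, fatty acid, WNT, fibroblast and leukocyte lists. The 13 genes of the mitochondrial genome were not analysed here.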

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

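The alternative without the genes of the shifted chromosome blocks was chosen after seeing the data, the others before. Genes past the threshold numbered 8485 to 11503 over all settings and 9826 to 10047 when 1 library was left out (10221 as reported). The stricter filter tests fewer genes. Leaving out 1 library gave 4082 to 4256 genes higher, 5693 to 5858 lower and 3331 to 3372 changed at least 2-fold. With median-of-ratios scaling 10192 genes passed, 5166 higher and 5026 lower, and 886 of the reported calls were not called in the same direction, 112 of these with a changed sign. The number of lists past the threshold was 15 to 17 in camera at the preset correlation, 1 with an estimated correlation and 26 with fry, which asks a different question. No shared effect of the replicate number was seen: same-numbered libraries deviated from their group means with correlations of 0.018, -0.018 and -0.055. Pairs with unlike numbers ranged from -0.050 to 0.066. Whether the numbers pair the libraries by design is not stated in the labels, and these values cannot decide it. A fit with the replicate block called 10192 genes, 10091 of them shared, and changed no list call.

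For named genes and lists, 1172 and 407 comparisons with an alternative kept direction and side of the threshold. SOX2, not past the threshold, ranged from -0.12 to 0.16 with 1 library left out (-0.12 without parental replicate 3, -0.059 without sphere replicate 2, -0.054 without sphere replicate 3). Camera's direction for the interferon list turned in 4 settings, never past the threshold, where its median relative to all genes was -0.038 with no filter, 0.031 at a mean of 5 TPM, 0.028 without parental replicate 1 and 0.039 without the blocks (0.028 to 0.087 with 1 library left out). That for the fibroblast list turned with no filter (median 0.012). The cause was not tested. The NF-kB list passed with no filter, at 5 TPM, with median-of-ratios scaling and without sphere replicate 1 or 3 (adjusted p from 0.0287 to 0.0434), and the stem cell list at 5 TPM (1.37, adjusted p = 0.0158, with fewer genes tested and most of its falling members removed by the filter). EGFL7 lost its call in 4 settings and H4C3 in 6. DESeq2 was not run, since TPM are not counts. Without known depth, counting error cannot be separated from other spread.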

Other observations

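All tests of the chromosome blocks and of other cell types were chosen after the result was seen; the splits of the libraries and the scaling test were planned. Among genes chosen after their values were seen, and not tested as a group, 3 of MHC class II antigen presentation differed between the groups. HLA-DRA was at 86.1 ± 3.6 TPM in parental and 6.82 ± 0.74 TPM in sphere libraries, CD74, the invariant chain, at 339 ± 9.3 and 41.4 ± 2.9 TPM, and HLA-DQB1 at 34.3 ± 2.7 and 1.05 ± 0.29 TPM (SD, n = 3 each). Under 0.5 TPM in each parental library and at least 5 TPM in each sphere library were 82 genes, and 29 showed the reverse.

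Neighbouring genes shifted together. Of 307 blocks, 13 had a median past the limit of 0.64 that permuted gene order sets, and 10 of them also passed with 1 gene per family, 7 higher and 3 lower in sphere libraries, among them the neighbours PHF20L1 to NRBP2 and EPPK1 to C8orf33 on chromosome 8 (medians 1.18 and 1.29 relative to all genes, with 95.1% of genes on that side in both), FBXO25 to INTS10 on chromosome 8 (-0.90) and PLEKHG4B to TRIO on chromosome 5 (-0.98). A family was taken as the genes of a block with the same letters before the first digit of the symbol. The tables argue against clustered families so defined as the whole cause, since 10 blocks passed with 1 gene per family. Related genes with unlike symbols were not joined, so clusters of these stay open. GC content, transcript length and expression level are also argued against as the whole cause, since 12 blocks passed after a fit on these, 9 of the 10 among them. The fit took 2.43% of the variance between genes, and MTG2 to PCMTD2 on chromosome 20 no longer passed. A chromosome dosage that differs between the cells of the 2 groups and regional regulation cannot be told apart, since both let adjacent blocks move alike (their medians correlated at 0.39 with 1 gene per family, a value examined after neighbouring blocks had been seen to shift together) and DNA was not measured here. The culture form itself also stays open and was not tested.

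VIM, CCL2 and the 3 MHC class II genes named above, known from mesenchymal or immune cells, were far higher in parental libraries, while the mesenchymal and leukocyte lists as such did not pass (camera adjusted p = 0.437 for both). Leukocytes mixed into the parental libraries are argued against by PTPRC, listed at 0 in each of these libraries. Fibroblasts as the source of most of the parental VIM are argued against by the fixed fibroblast list, whose 10 members with values had a median of at most 0.058% of the VIM TPM in a parental library, with COL1A2 at 0.76, LUM at 0.42 and PDGFRA at 0.26 TPM on average and COL3A1 at 0, under bounds of a hundredth and a thousandth set after these values were seen. PDGFRB went the other way, falling with VIM from 2.63 to 0.087 TPM. Of the 10 members, 4 were higher on average in sphere libraries. With bounds set this late, the list is weak evidence. A smaller admixture of fibroblasts cannot be told apart from expression by the cancer cells, as COL1A1, COL1A2 and COL3A1 came to at most 1.45% of the VIM TPM, between the tenth that fibroblasts were taken to need and the hundredth taken to exclude them, and most of this was COL1A1, which was higher in sphere libraries. The difference in culture form stays open and untested.

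More genes were lower than higher in sphere libraries (42.2% of calls higher). The 100 highest genes held 34.2 to 34.6% of TPM in parental and 38.8 to 39.5% in sphere libraries. Median-of-ratios scaling gave 50.7% of calls higher, and 56.2% of the 2-fold calls against 46.0% as reported, but it sets the typical gene near 0 by construction, so this near-even split decides nothing. A few genes taking a larger share of the transcripts and a lower level of most genes cannot be told apart, and TPM cannot show a difference in total RNA per cell.

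Of the 10 splits of the 6 libraries into 3 and 3, the real one called 10221 genes and the highest of the others 0 in limma, and 1 of 10 was as large as the real one, itself. With 10 splits the share cannot go below 0.1.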
